A study of Homo sapiens with 12 samples.

How the data were processed

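Polyadenylated RNA of HEK-293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was sequenced in 12 libraries that fall into 4 groups of 3. Per the labels, the cells held 1 of 2 CIRTS effectors, named a nuclease (CIRTS-12) and YTHDF2 (CIRTS-3), and either a non-targeting guide RNA or a guide against SMARCA4. RNA was extracted with an RNeasy kit and libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols. The series calls the samples of a group biological replicates. No label says how the cultures were grown or transfected, or in which batches, so p-values measure the spread between these samples, and the effector cannot be told apart from any batch that went with it.

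The authors deposited 1 table per library with an estimated count for each of 200403 targets, made with kallisto per the submitters' processing notes, which also name sleuth and the hg38 build without versions. The deposited TPM values in the same tables are, per the file headers, kallisto's length-normalized abundances, which divide the estimated counts by effective length and keep no depth. The targets are 200401 transcripts with gene IDs, symbols and biotypes, and 2 luciferase reporters, firefly and renilla. The effective length was the length minus 179 bases for 91.3% of targets. Kallisto shares reads among transcripts with the same sequence, so a plasmid-borne coding sequence is counted on whichever transcripts share its bases, and near-identical genes (HSPA1A and HSPA1B, pseudogenes and their parents) trade counts. The strand setting is not given in the sources used here, so genes and their antisense partners may also share counts.

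Estimated counts were summed over the transcripts of each of 58288 gene IDs and rounded to whole numbers. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and 1 mean per group over all 12 libraries. The fit kept 16297 genes, which hold at least 99.8% of the counts of every library, with 8 residual degrees of freedom and a biological coefficient of variation of 11.4%. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Levels are CPM, counts scaled by TMM-adjusted library totals, given as mean ± SD, n = 3. Single values were also compared by an exact permutation test, whose smallest two-sided p for 3 against 3 is 0.1. The same model was fitted to 49518 transcripts. The 5 comparisons were the SMARCA4 guide against the non-targeting guide with each effector, the difference of those effects (the interaction), and YTHDF2 against the nuclease with each guide.

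Library totals ranged from 9207196 to 18047859 estimated counts. The fit was tested on simulated counts, drawn from the real means, totals and dispersions, with 50 changed genes per fold among genes of moderate or high expression. Apart from the simulated change, each gene had 1 mean and 1 dispersion for all groups, and genes were drawn independently. The wider spread and shared trends of the YTHDF2-NT libraries were thus not simulated, so recovery in comparisons with them may be overstated. For the nuclease comparison, over 15953 genes, it recovered 18% of genes changed 1.25-fold, 72% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 10 false calls among 151. For the YTHDF2 comparison, over 15913 genes, it recovered 14%, 60%, 92% and 100% at those folds, with 5 false calls among 138. Intervals are for 95% confidence.

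Named genes followed a rule. SMARCA4 was given in every library. Among called genes with at least 1 CPM in the higher group and no overlap between the groups' libraries, the 10 largest increases and decreases were taken per comparison, and with fewer than 10 also the 10 smallest p-values, as values. All genes of a list of possible construct parts, set from general knowledge of such effectors since the labels do not give the parts, and, in each other list, the 2 members with the smallest p were taken, and symbols shared by several gene IDs were skipped. Members that passed with adjustment over the list alone were taken as further examples, a reading of the rule made after the values were seen. Of 25 gene lists, 24 had measured members: BAF subunits, construct parts, neighbours of SMARCA4, m6A machinery, deadenylation and decay factors, nonsense-mediated decay (NMD) factors and targets, interferon response, integrated stress, unfolded protein response, heat shock, immediate early genes, p53 targets, cholesterol synthesis, hypoxia and glycolysis, G1/S genes, G2/M genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, nuclear-encoded respiratory chain subunits, replication histones, and markers of fibroblasts, epithelium and blood. Liver markers had 0 of 10 members past the count filter. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. In the nuclease guide comparison the estimated correlation was 0.974 for ribosomal proteins, 0.932 for respiratory subunits and 0.644 for hypoxia and glycolysis. For such lists the preset correlation gives p-values that are too small, and members are not independent.

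The groups, tests, lists and naming rule, and most alternatives, were chosen before the data were examined. Those alternatives were other size factors, other count filters, DESeq2 1.42.0, only the 6 libraries compared, a replicate block, length-scaled TPM counts, limma-trend on log2(TPM + 0.5), protein-coding genes only, and each library left out in turn. Removal of per-library trends on transcript length and on GC (loess, span 0.3), leaving out each YTHDF2 library with the non-targeting guide from fits of comparisons without them, leaving out 1 of these together with the length trend, and list tests with the length trend removed or with the block, were added after seeing the data. Coordinates and transcript sequences are from GENCODE v29 on GRCh38, where 200154 of the transcripts (99.9%) were matched by ID. The output of sleuth was not used here. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.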

Results

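Messenger RNA was measured in 12 libraries of HEK-293T cells that carried a CIRTS protein, an effector built from human protein parts and steered to an RNA by a guide. The series compares a guide against SMARCA4, which encodes the BRG1 ATPase of the BAF chromatin remodelling complexes, with a non-targeting (NT) guide, for a nuclease effector and for an effector made with YTHDF2, a reader of m6A that recruits deadenylases to mRNA. The 4 groups of 3 libraries are called nuclease-NT, nuclease-SMARCA4, YTHDF2-NT and YTHDF2-SMARCA4 here. A value given for a gene or as a list's median without a unit is a log2 fold change, of the SMARCA4 guide over the NT guide or of YTHDF2 over the nuclease. A list that is said to be higher, lower or called passed camera unless its adjusted p is above 0.05, and single members are values unless said to pass. Total estimated counts were 12522563, 14217701 and 9207196 in nuclease-NT, and 13883018, 14572824 and 12259533 in nuclease-SMARCA4. They were 13902130, 11955353 and 14313712 in YTHDF2-NT, and 11744214, 14205603 and 18047859 in YTHDF2-SMARCA4. Between 23001 and 25583 genes had at least 1 count in a library, and the 10 most abundant genes held 5.01 to 6.43% of the counts. EEF1A1, a translation elongation factor, held the most counts in every library except YTHDF2-NT 1, where ZPR1 did. In that library 1 ZPR1 transcript model with a run of 35 T was at 28313 TPM, against 59.0 for the other ZPR1 transcripts together. Whether those reads come from ZPR1 mRNA was not tested. The libraries of YTHDF2-NT stood apart from each other. On the first principal component, which held 45.3% of the variance, YTHDF2-NT 1 lay at 34.7 and YTHDF2-NT 2 at −18.2. Across 10457 genes the deviation from the mean of all libraries ranked with transcript length at a Spearman rho of −0.65 in YTHDF2-NT 1, 0.64 in YTHDF2-NT 2 and −0.34 in YTHDF2-NT 3. With GC content the rho was 0.42, −0.63 and 0.04 in these libraries, and −0.37, −0.47 and −0.33 in YTHDF2-SMARCA4. It was 0.05, 0.02 and 0.14 in nuclease-NT and 0.03, 0.53 and 0.13 in nuclease-SMARCA4.

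**Figure D1:**
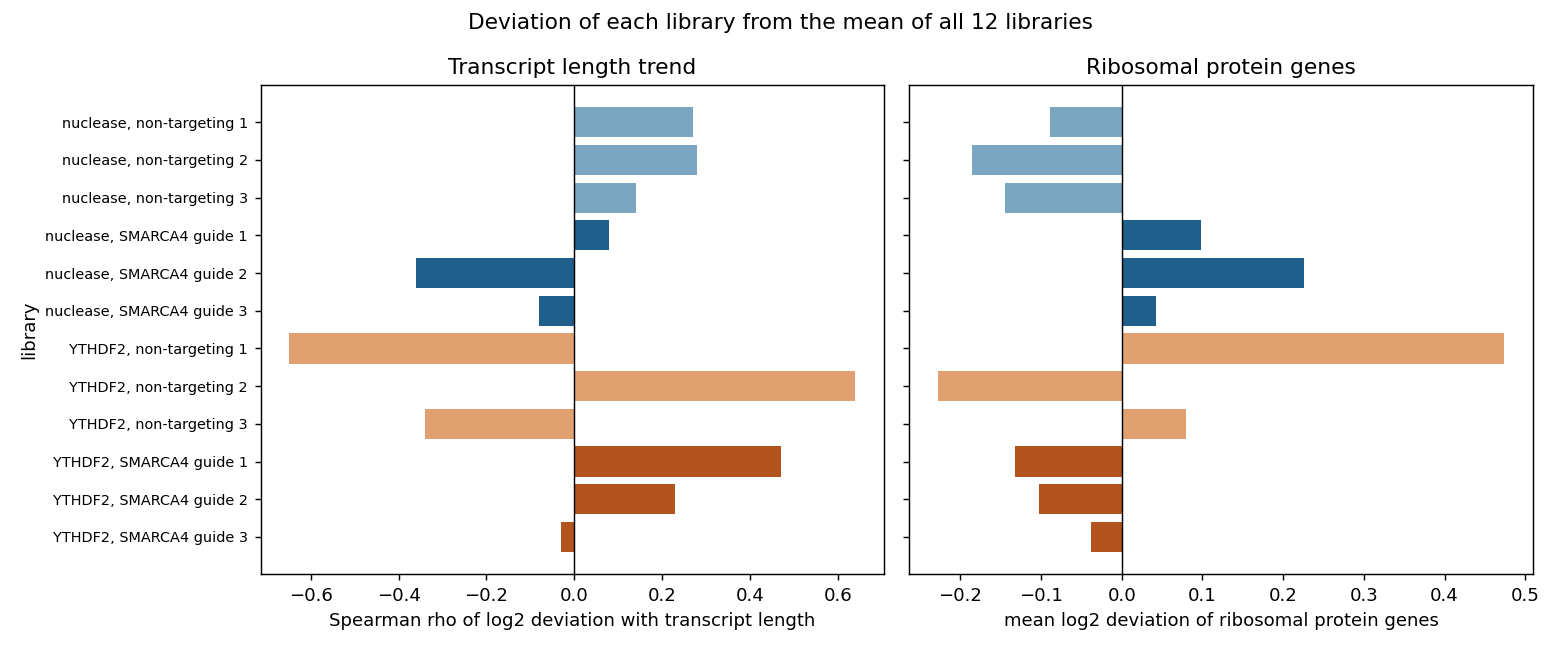
Spearman correlation across 10457 genes between each library's deviation from the mean of all libraries and transcript length, and the mean deviation of the cytosolic ribosomal protein mRNAs in the same library. YTHDF2-NT 1 (rho −0.65) and YTHDF2-NT 2 (rho 0.64) lie at opposite ends, with ribosomal deviations of 0.47 and −0.23 on the log2 scale.

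SMARCA4 mRNA (ENSG00000127616.18, chromosome 19, 10960825 to 11079426, plus strand, GRCh38) differed between guides by less than the spread between replicates in the nuclease cells, and in the YTHDF2 cells its lower mean with the SMARCA4 guide did not pass the test over all genes. Its level was 225.4, 245.1 and 242.2 CPM in nuclease-NT and 238.8, 250.0 and 219.6 CPM in nuclease-SMARCA4, or 237.6 ± 10.7 against 236.1 ± 15.4 (SD, n = 3). In YTHDF2-NT it was 302.4, 234.8 and 250.2 CPM, and in YTHDF2-SMARCA4 243.4, 210.2 and 220.6 CPM, or 262.5 ± 35.4 against 224.8 ± 17 (SD, n = 3). The log2 fold change for the SMARCA4 guide was −0.01 (SE 0.095, edgeR quasi-likelihood adjusted p = 0.985) with the nuclease, and its 95% interval ran from −13.7% to 14.6%. With YTHDF2 it was −0.22 (SE 0.095, unadjusted p = 0.0337, adjusted p = 0.703), or −14.4% with an interval from −25.7% to −1.4%. That interval rests on a spread shared by all groups, while the SD was 35.4 CPM in YTHDF2-NT and 10.7 CPM in nuclease-NT. It may thus be too narrow for the YTHDF2 comparison. Exact permutation tests gave p = 0.9 and p = 0.2, where 0.1 is the smallest value 3 against 3 can give. The effects differed by −0.22 (SE 0.134, adjusted p = 0.552), so a difference between effectors was not shown. SMARCA2, the other ATPase of BAF complexes, was at 27.2, 26.1, 28.6 and 29.2 CPM in the 4 groups (adjusted p = 0.914 with the nuclease and 0.968 with YTHDF2). None of the SMARCA4 transcripts was called. The nuclease value turned positive without nuclease-NT 2 (0.01), nuclease-NT 3 (0.003) or nuclease-SMARCA4 3 (0.04). The YTHDF2 value passed the test without YTHDF2-NT 2 (−0.29, adjusted p = 0.0485) and was −0.11 without YTHDF2-NT 1. Of 18 alternatives it passed only in the fit without YTHDF2-NT 2. That fit called 1585 genes in this comparison, and its fold changes ranked with transcript length at a Spearman rho of 0.6 across 10486 genes.

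**Figure D2:**
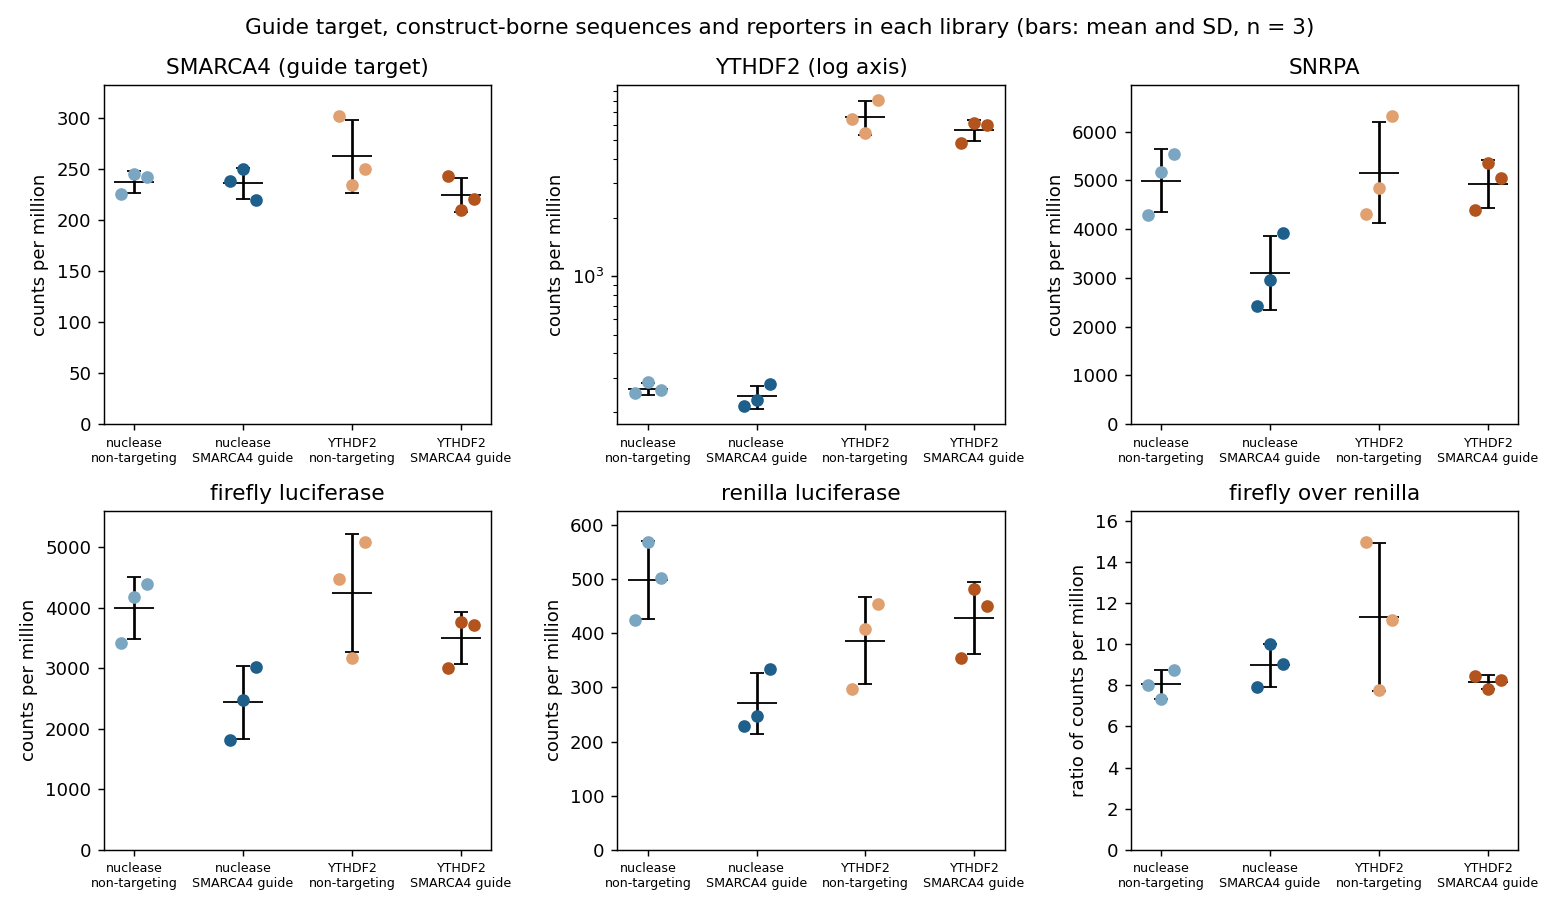
CPM of SMARCA4, YTHDF2 (log axis), SNRPA and the firefly and renilla luciferase targets, and the ratio of the reporters, in each library (points), with the mean and SD of each group (bars, n = 3). SMARCA4 lies between 210.2 and 302.4 in all libraries, YTHDF2 is raised in both YTHDF2 groups, and both reporters and SNRPA are lowest in nuclease-SMARCA4.

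Of the genes that a construct can carry, YTHDF2 was raised wherever its effector was used. YTHDF2 (chromosome 1, 28736621 to 28769775, plus strand) was at 263.6 ± 17.9 and 240.8 ± 32.7 CPM in nuclease-NT and nuclease-SMARCA4, and at 6619 ± 1310 and 5653 ± 724 CPM in the YTHDF2 groups (SD, n = 3), 25.1-fold and 23.5-fold higher. This gene rose with both guides (log2 4.65, SE 0.161, adjusted p = 3.69e-09 with the NT guide, and 4.55, SE 0.16, adjusted p = 4.57e-09 with the SMARCA4 guide). The labels do not give the parts of the constructs. Nearly all of the difference lay on 1 transcript model of 657 bases, which spans 479 of the 1587 coding bases of a full-length model. It was at 6240 and 5420 CPM in the YTHDF2 groups against 0.228 and 0.413 CPM in the nuclease groups. SNRPA (chromosome 19, 40750637 to 40765389, plus strand), which encodes a protein of the U1 snRNP of the spliceosome, was at 4996 ± 645, 3094 ± 755, 5160 ± 1040 and 4928 ± 496 CPM in nuclease-NT, nuclease-SMARCA4, YTHDF2-NT and YTHDF2-SMARCA4 (SD, n = 3). Most of it lay on SNRPA-206, which spans 426 of 846 coding bases and was at 4010 and 2480 CPM in the nuclease groups, while SNRPA-201 was at 132 and 135 CPM.

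Firefly and renilla luciferase, reporter genes absent from human cells, were counted in every library. Firefly was at 3993 ± 517, 2437 ± 605, 4242 ± 980 and 3491 ± 429 CPM, and renilla at 498.2 ± 72.8, 270.3 ± 55.9, 386.4 ± 80.5 and 428.7 ± 66.5 CPM, in the same order of groups (SD, n = 3). Neither passed the test over all genes in the nuclease guide comparison (firefly −0.71, SE 0.189, adjusted p = 0.214, renilla −0.88, SE 0.177, adjusted p = 0.142). SNRPA did not either (−0.69, SE 0.171, adjusted p = 0.2). Adjusted over the list alone, SNRPA (adjusted p = 0.00672) and SMG6, which encodes an endonuclease of NMD (−0.33, adjusted p = 0.0213, 48.1 against 38.2 CPM), passed in that comparison. SMG6 was at 41.4 and 41.2 CPM in YTHDF2-NT and YTHDF2-SMARCA4, between its values in the nuclease groups. In a fit of the 6 nuclease libraries alone, renilla (adjusted p = 0.0117), firefly and SNRPA (both 0.0244) and SMG6 (0.0455) passed. Firefly, renilla and SNRPA also passed with DESeq2 (0.0265, 0.00129 and 0.0172) and without a filter on low counts (7.72e-14, 4.32e-18 and 3.2e-13). The fit without a filter called many more genes than the main fit in every comparison, so its small values are not specific to these 3. Renilla passed without YTHDF2-NT 1 (0.0317) and with GC and length trends removed (0.0355), and with the length trend removed and YTHDF2-NT 2 left out renilla (0.0296) and firefly (0.0354) passed. In the YTHDF2 guide comparison firefly was at −0.28 (adjusted p = 0.729), renilla at 0.15 (adjusted p = 0.833) and SNRPA at −0.07 (adjusted p = 0.93). The difference between effectors was not called for renilla (1.03, adjusted p = 0.25), SNRPA (0.63, adjusted p = 0.411) or firefly (0.43, adjusted p = 0.55). HBEGF, a growth factor, was at 5.13, 4.44, 6.35 and 6.34 CPM and YTHDF1, a paralog of YTHDF2, at 71.4, 63.4, 75.5 and 74.2 CPM. DEFB103A and DEFB103B, which encode a defensin, had 0 counts in every library.

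With the nuclease, p53 targets, genes that p53 switches on in stressed cells, were lower with the SMARCA4 guide than with the NT guide. The activity of p53 was not measured, and these cells carry the SV40 large T antigen. The list thus names genes rather than a p53 response. Of 16 measured members 15 were lower, with a median log2 fold change of −0.28 (camera adjusted p = 2.22e-08, adjusted p = 0.143 with an estimated correlation). Adjusted over the list alone 8 passed, against 0 over all genes. FAS, a death receptor, was at −0.57, PLK3, a stress kinase, at −0.95, GDF15, a stress cytokine, at −0.68, and MDM2, the ubiquitin ligase that restrains p53, at −0.32. Replication histone genes, whose mRNAs mostly lack a poly(A) tail, were also lower, 8 of 11 with a median of −0.31 (adjusted p = 0.000654, adjusted p = 0.163 with an estimated correlation). Over the list alone 4 passed, among them HIST1H2AC (−0.92) and HIST1H4H (−1.40). G2/M genes rose as a list, 15 of 17 with a median of 0.14 (adjusted p = 0.000344, adjusted p = 0.127 with an estimated correlation). AURKA and PLK1, mitotic kinases, were at 0.19 and 0.17. The mean deviation of p53 targets from all libraries was 0.10, 0.33 and 0.24 in nuclease-NT, against −0.18, −0.08 and 0.03 in nuclease-SMARCA4 and −0.12 to −0.02 in the 6 YTHDF2 libraries. All 3 lists passed in each of 6 fits that left out 1 compared library, with medians from −0.32 to −0.22 for p53 targets.

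Genes of glycolysis and the hypoxia response were higher in the same comparison, 18 of 19 with a median of 0.36 (adjusted p = 2.22e-08, adjusted p = 0.361 with an estimated correlation). Of these 4 passed over the list alone. PGK1 (0.45) and LDHA (0.48) encode glycolytic enzymes, PFKFB4 (0.70) a regulator of glycolysis and NDRG1 (0.79) a hypoxia-induced protein. Cytosolic ribosomal protein mRNAs were higher in 35 of 35 cases (median 0.27, adjusted p = 3.3e-14, adjusted p = 0.404 with an estimated correlation), with RPL7A at 0.32 and RPL3 at 0.26. Nuclear-encoded respiratory chain subunits were higher in 22 of 22 (median 0.16, adjusted p = 0.000544, adjusted p = 0.508 with an estimated correlation). SDHB was at 0.19 and COX4I1 at 0.26. These short mRNAs moved with the length trend of the libraries, which was 0.27, 0.28 and 0.14 in nuclease-NT and 0.08, −0.36 and −0.08 in nuclease-SMARCA4. With that trend removed, the ribosomal median was 0.17 and the respiratory median 0.06. The hypoxia median was 0.18 (adjusted p = 0.0026) without nuclease-SMARCA4 1.

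The other lists that passed did so with small medians. NMD targets, mRNAs degraded by nonsense-mediated decay, were lower in 14 of 20 (median −0.10, adjusted p = 0.00181, adjusted p = 0.488 with an estimated correlation). SRSF6 (−0.53), a splicing factor, and the snoRNA host genes SNHG15 (−0.66) and SNHG12 (−0.72), 3 members, passed over the list alone. NMD factors were lower in 11 of 13 (−0.13, adjusted p = 0.014, adjusted p = 0.318 with an estimated correlation). SMG5 was at −0.23 and UPF2 at −0.19. G1/S genes were lower in 12 of 17 (−0.07, adjusted p = 0.0191, adjusted p = 0.43 with an estimated correlation). CDC6 and MCM3, which license replication, were at −0.27 and −0.18. Members of the unfolded protein response were higher in 12 of 16 (0.10, adjusted p = 0.0389, adjusted p = 0.403 with an estimated correlation). Construct parts were lower in 5 of 5 (−0.21, adjusted p = 0.000716, adjusted p = 0.323 with an estimated correlation), and at −0.12 without nuclease-SMARCA4 1. The list holds possible parts, and in these cells the YTHDF2 transcript model raised by its effector was at 0.228 and 0.413 CPM. A fall of the list is thus not a measure of a construct. Calls were lost for NMD targets without nuclease-SMARCA4 1 (−0.02, adjusted p = 0.228). They were lost for NMD factors and G1/S genes without nuclease-NT 3 (adjusted p = 0.085 and 0.0934) or nuclease-SMARCA4 1 (0.0578 and 0.0702). The unfolded protein response lost its call without nuclease-NT 1 (0.0861), nuclease-NT 2 (0.121) or nuclease-SMARCA4 3 (0.131). The NMD target median was −0.15 without nuclease-NT 1, −0.17 without nuclease-SMARCA4 2 and −0.16 with the length trend removed.

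BAF subunits, the partners of the target, were not called (median −0.06, adjusted p = 0.358, BRD7 0.14, ARID1B −0.25), nor were the neighbours of SMARCA4 (0.07, adjusted p = 0.283, SPC24 0.25, CARM1 0.11). The m6A machinery (−0.10, adjusted p = 0.0774, YTHDF1 −0.17, YTHDC1 −0.14), deadenylation and decay factors (−0.09, adjusted p = 0.0668, CNOT10 −0.27, EDC4 −0.19) did not pass. Neither did integrated stress genes (0.08, adjusted p = 0.22, MTHFD2 0.18, VLDLR 0.55), heat shock genes (−0.10, adjusted p = 0.342) and immediate early genes (0.17, adjusted p = 0.163). Cholesterol synthesis (0.04, adjusted p = 0.172, INSIG1 0.29) and mitochondrially encoded mRNAs (−0.05, adjusted p = 0.339, MT-ND1 −0.29) were not called either. Interferon response genes had a median of −0.01 and a mean of 0.09, which differ in sign (adjusted p = 0.491). IFI44L was at 1.70 and ISG20 at −0.70. Markers of fibroblasts were at 0.10 (5 of 5 higher, adjusted p = 0.0572, PDGFRA 1.18). Those of epithelium were at −0.11 (adjusted p = 0.88) and those of blood at −0.21 (4 of 4 lower, adjusted p = 0.391, CD14 −0.71). The fibroblast list passed without nuclease-NT 1 (0.36), nuclease-NT 3 (0.25) or nuclease-SMARCA4 1 (0.24). Mitochondrially encoded mRNAs passed without nuclease-NT 3 (−0.20) or nuclease-SMARCA4 2 (−0.22), cholesterol synthesis without nuclease-SMARCA4 2 (adjusted p = 0.038) and integrated stress without nuclease-SMARCA4 1 (adjusted p = 0.00381).

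Among single genes, edgeR called only ZNF767P in the nuclease guide comparison, a pseudogene of a zinc finger gene (chromosome 7, 149547154 to 149624752, minus strand), which fell from 49.1 ± 6.29 to 22.6 ± 2.78 CPM (SD, n = 3), a log2 fold change of −1.12 (SE 0.141, adjusted p = 0.035). Its counts can be shared with related genes, and it was at 29.2 and 31.5 CPM in the YTHDF2 groups. The next smallest p-values belonged to CPT1B, a carnitine transferase (−0.76), PRKAB1, an AMPK subunit (−0.53), and MCOLN3, an ion channel (−0.82), all at an adjusted p of 0.0813. They were followed by POMZP3 (−1.04), DDB2, a p53-regulated repair factor (−0.77, 89.7 against 52.7 CPM), LRRC37A2 (−0.49), HSD17B7P2 (−1.14), AC008440.2 (1.5) and AC073869.1 (−0.73). At an unadjusted p under 0.05 there were 1783 genes where chance gives 815. No overlap between the groups was seen for 25.1% of genes, where chance gives 10%. Genes share trends of the libraries and are not independent. Such counts and shares can thus lie far from the chance values without an effect of guide or effector, here and in the other comparisons. The biological coefficient of variation was 11.4% in the fit of 12 libraries, 14.4% in a fit of the 6 YTHDF2 libraries and 6.8% in a fit of the 6 nuclease libraries. That last fit called 550 genes (259 higher, 291 lower), and DESeq2 called 129. The call of ZNF767P was lost without nuclease-NT 2, nuclease-NT 3, any 1 of the nuclease-SMARCA4 libraries or YTHDF2-NT 3 (log2 −1.05, −1.07, −1.02, −1.14, −1.19 and −1.12 in that order). It was also lost with length-scaled TPM counts (−1.07) and limma (−1.14). Without YTHDF2-NT 1 and YTHDF2-NT 2, which are not in this comparison, 44 and 27 genes were called.

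**Figure D3:**
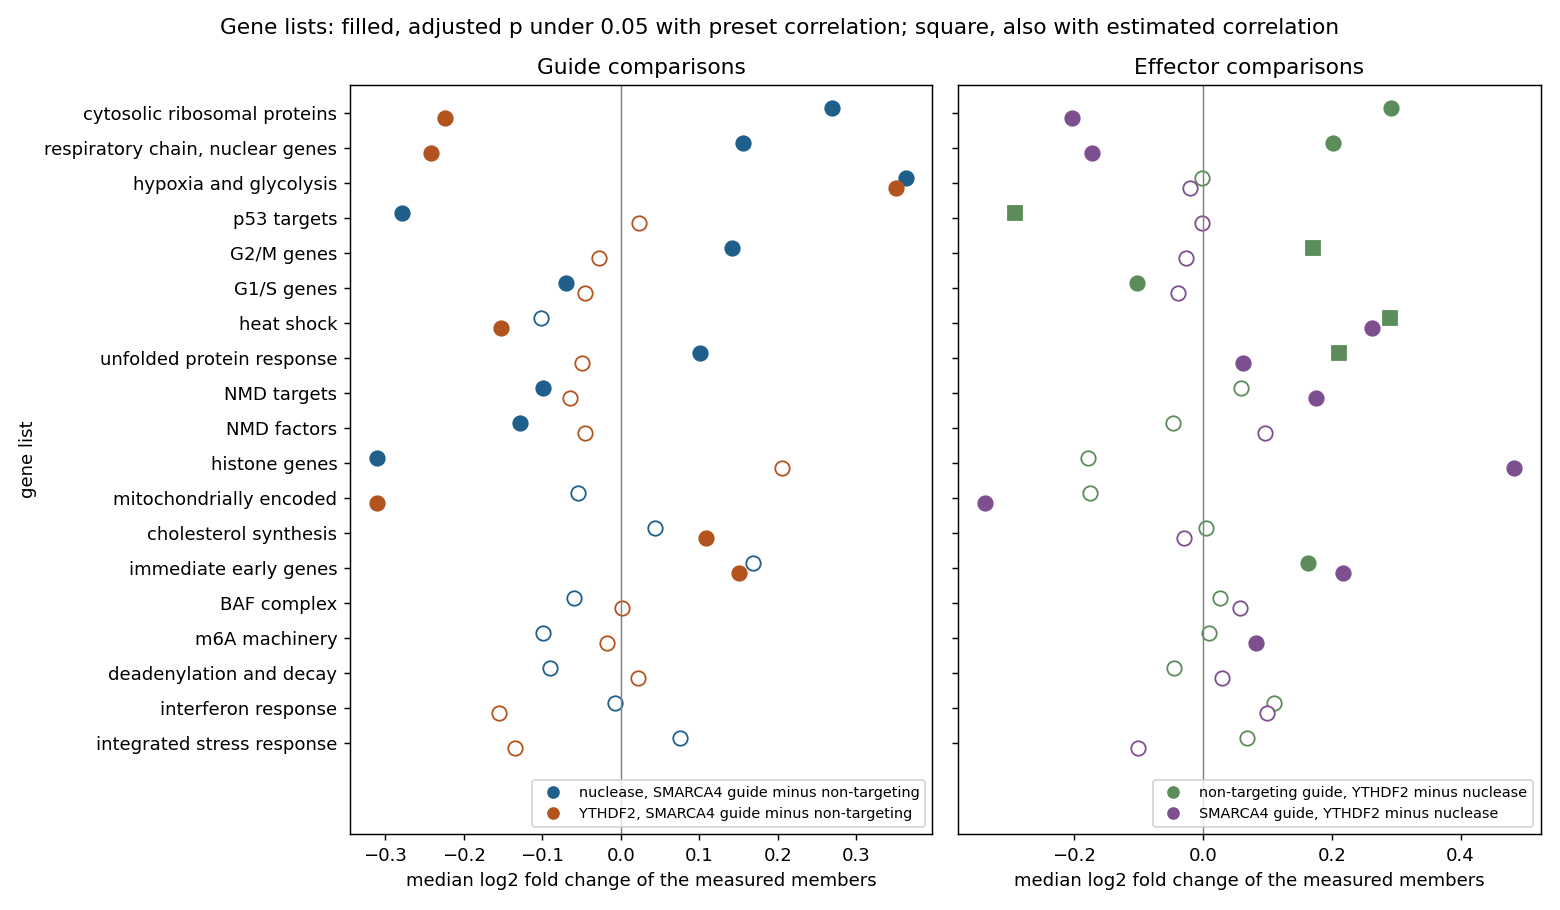
Median log2 fold change of the measured members of 19 gene lists in the guide comparisons (left) and the effector comparisons (right). Filled symbols passed at an adjusted p under 0.05 with the preset correlation and squares also with an estimated correlation, which among these lists are the p53, G2/M, heat shock and unfolded protein lists of the effector comparison with the NT guide.

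With YTHDF2 as effector, 7 lists passed between the guides and no single gene did. Hypoxia and glycolysis genes were higher, 17 of 19 with a median of 0.35 (adjusted p = 3.08e-09, adjusted p = 0.715 with an estimated correlation). NDRG1 was at 0.77 and the glucose transporter SLC2A1 at 0.67. Heat shock genes, protein-folding chaperones, were lower in 9 of 12 (median −0.15, adjusted p = 0.00134, adjusted p = 0.679 with an estimated correlation). HSP90AA1 (−0.38) passed over the list alone. Cholesterol synthesis genes were higher in 14 of 19 (0.11, adjusted p = 0.0052, adjusted p = 0.679 with an estimated correlation), with SC5D at 0.30 and DHCR7 at 0.19. Immediate early genes, the first to answer growth signals, were higher in 12 of 16 (0.15, adjusted p = 0.0335, adjusted p = 0.813 with an estimated correlation). FOS was at 0.70 and KLF6 at −0.25. Ribosomal protein mRNAs were lower in 35 of 35 (−0.22, adjusted p = 5.94e-10, RPL7 −0.32, RPL6 −0.24). So were respiratory chain subunits in 22 of 22 (−0.24, adjusted p = 1.32e-05, COX6C −0.27, NDUFS5 −0.31) and mitochondrially encoded mRNAs in 11 of 13 (−0.31, adjusted p = 0.00134, MT-ND3 −0.64, MT-CO3 −0.48), each at adjusted p = 0.813 with an estimated correlation.

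The short-mRNA lists of this comparison moved with the YTHDF2-NT libraries that stood apart. Without YTHDF2-NT 1 the ribosomal median was −0.02 (adjusted p = 0.473) and the respiratory median 0.001 (adjusted p = 0.622). They were −0.38 and −0.39 without YTHDF2-NT 2, and with the length trend removed −0.06 (adjusted p = 0.000977) and −0.04 (adjusted p = 0.369). Mitochondrially encoded mRNAs lost their call without YTHDF2-NT 2 (−0.17, adjusted p = 0.772), without YTHDF2-SMARCA4 1 (−0.14, adjusted p = 0.219) or with the length trend removed (adjusted p = 0.0508). Cholesterol synthesis lost it without YTHDF2-SMARCA4 1 (adjusted p = 0.0575). Its median was 0.05 without YTHDF2-NT 1, 0.18 without YTHDF2-NT 2, 0.17 without YTHDF2-SMARCA4 3 and 0.07 with the length trend removed. Immediate early genes lost it without YTHDF2-NT 1 (0.04, adjusted p = 0.115), YTHDF2-NT 2 (adjusted p = 0.606) or YTHDF2-SMARCA4 1 (adjusted p = 0.4), and with the length trend removed (adjusted p = 0.0508). The hypoxia list kept its call in each fit, at 0.22 without YTHDF2-SMARCA4 1, and the heat shock list kept it at −0.09 without YTHDF2-NT 3 and −0.10 without YTHDF2-SMARCA4 1.

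The BAF list was at 0.002 (adjusted p = 0.913, SMARCB1 −0.18), construct parts at −0.03 (adjusted p = 0.753), the neighbours at 0.04 (adjusted p = 0.753), and decay factors at 0.02 (adjusted p = 0.895). P53 targets were at 0.02 (adjusted p = 0.753), G1/S genes at −0.05 (adjusted p = 0.753), and unfolded protein genes at −0.05 (adjusted p = 0.525). Interferon genes were at −0.16 (adjusted p = 0.895), fibroblast markers at −0.08 (adjusted p = 0.895) and blood markers at −0.13 (adjusted p = 0.773), and none of these lists was called. Medians and means differed in sign for G2/M genes (−0.03 and 0.002), the m6A machinery (−0.02 and 0.003, both adjusted p = 0.895) and epithelial markers (−0.21 and 0.10, adjusted p = 0.753, EPCAM −0.57). NMD factors were at −0.05 and NMD targets at −0.07, and the latter passed without YTHDF2-NT 2 (−0.17, adjusted p = 0.0162). Histone genes (0.21, adjusted p = 0.0657, with HIST1H2AC at 0.59 past the test over the list alone) and integrated stress genes (−0.14, adjusted p = 0.0657) did not pass. Both passed without YTHDF2-NT 1 (adjusted p = 0.00723 and 0.0216) or YTHDF2-SMARCA4 1 (0.0214 and 0.0347), the first also without YTHDF2-NT 3 (0.0053) and the second without YTHDF2-NT 2 (0.0484). With the length trend removed both passed (0.00665 and 0.0187). The histone median was 0.36 without YTHDF2-NT 3. Without YTHDF2-NT 1 the m6A machinery and decay factors passed as lower lists with the preset correlation, both at −0.07 (0.0333 and 0.0329), which turned the sign of the decay factors. With all libraries and an estimated correlation both were at a camera adjusted p of 0.923.

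No gene was called by edgeR (0 of 16297, smallest adjusted p = 0.703), while 1112 had an unadjusted p under 0.05, DESeq2 called 1 and limma 0. The 10 smallest p-values included MRI1, a methionine salvage enzyme (0.35, 43.7 against 55.5 CPM), HNRNPM, a splicing factor (−0.39, 585 against 448 CPM), ZFHX4 (−0.43), SEC31B (0.80) and LGALS8, a galectin (−0.88). The others were AL136982.4 (3.75), AC092171.2 (−0.56), AC242426.3, AC009244.1 and AC010422.3, whose mean was 2.89 CPM in YTHDF2-NT and 0 in YTHDF2-SMARCA4. Groups did not overlap for 9.3% of genes, where chance gives 10%. Without YTHDF2-NT 2 the fit called 1585 genes (648 higher, 937 lower), and their fold changes then ranked with transcript length at a Spearman rho of 0.6 across 10486 genes. Simulated genes changed 1.5-fold were recovered in 60% of cases in this comparison. The simulation used 1 spread per gene for all groups, so that share may be too high here. The biological coefficient of variation was 14.4% in a fit of these 6 libraries and 6.8% in a fit of the 6 nuclease libraries.

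Guide effects of the effectors differed for 5 lists with all 12 libraries. P53 targets were higher in the YTHDF2 effect than in the nuclease effect for 14 of 16 members (median difference 0.27, adjusted p = 2.53e-05, adjusted p = 0.278 with an estimated correlation), with FAS at 0.92 and PLK3 at 1.17. Histone genes were higher for 8 of 11 (0.79, adjusted p = 0.000207, adjusted p = 0.278 with an estimated correlation, and 0.04 with the length trend also removed). HIST1H2AC was at 1.51 and HIST1H1C at 0.80. Lower differences were found for 35 of 35 ribosomal protein mRNAs (−0.49, adjusted p = 2.4e-21, adjusted p = 0.524 with an estimated correlation), of which 32 passed over the list alone. The same held for 22 of 22 respiratory chain subunits (−0.40, adjusted p = 1.27e-07, adjusted p = 0.662 with an estimated correlation) and for 13 of 17 G2/M genes (−0.14, adjusted p = 0.0305, adjusted p = 0.278 with an estimated correlation). UBE2C was at −0.37 and TOP2A at −0.23. The estimated correlation between members was 0.975 for the ribosomal and 0.934 for the respiratory list. Members of these lists are thus not independent results, however many of them pass. The ribosomal difference was −0.28 and the respiratory one −0.17 without YTHDF2-NT 1, and −0.24 and −0.07 with the length trend removed. G2/M genes lost the call without YTHDF2-NT 2 (adjusted p = 0.23), YTHDF2-SMARCA4 1 (0.0516) or nuclease-NT 3 (0.0591). Hypoxia and glycolysis genes, which passed with both effectors, had a difference of −0.001 (adjusted p = 0.814). Heat shock genes, which passed with YTHDF2, had a median difference of −0.001 and a mean of −0.09 (adjusted p = 0.225), with 6 of 12 members lower. Over the list alone 3 passed, all lower: HSPB1 (−0.81), HSP90AA1 (−0.48) and HSPD1 (−0.25).

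With the preset correlation, the difference also passed for other lists without single libraries or with the length trend removed. With an estimated correlation none of them passed, either with all 12 libraries (camera adjusted p from 0.597 to 0.785) or in those fits. For NMD targets (0.10, adjusted p = 0.117) it passed without YTHDF2-NT 1 (adjusted p = 0.00123), YTHDF2-NT 3 (0.015), nuclease-NT 1 (0.0256), nuclease-SMARCA4 2 (0.0385) or nuclease-SMARCA4 3 (0.0204), and with the trend removed (2.07e-05). Integrated stress genes (−0.22, adjusted p = 0.056) passed without YTHDF2-NT 1 (0.0154), YTHDF2-NT 2 (0.0453), YTHDF2-SMARCA4 1 (0.0265), nuclease-NT 2 (0.0397), nuclease-NT 3 (0.0419) or nuclease-SMARCA4 1 (0.000838). Unfolded protein genes (−0.17, adjusted p = 0.056) passed without YTHDF2-NT 1 (0.0135), YTHDF2-NT 2 (0.0453), YTHDF2-SMARCA4 1 (0.0256), nuclease-NT 3 (0.0419), nuclease-SMARCA4 1 (0.0352) or nuclease-SMARCA4 2 (0.0409), and both lists with the trend removed (−0.20 and −0.10, both 0.0122). Construct parts (0.21, adjusted p = 0.0945) did without YTHDF2-NT 3 (0.0342), YTHDF2-SMARCA4 1 (0.0256), nuclease-NT 1 (0.0401) or nuclease-SMARCA4 3 (0.0187). Mitochondrially encoded mRNAs (−0.13, adjusted p = 0.225) did without YTHDF2-NT 3 (−0.24, adjusted p = 0.0376), YTHDF2-SMARCA4 3 (−0.27, 0.0407), nuclease-NT 2 (−0.23, 0.0237) or nuclease-SMARCA4 3 (−0.28, 0.0187). G1/S genes (0.04, adjusted p = 0.225) did without YTHDF2-NT 1 (0.07, adjusted p = 0.0193).

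The edgeR interaction test called 0 genes, with 1802 at an unadjusted p under 0.05, 53 called by DESeq2 and 2 by limma. Its smallest adjusted p was 0.0985, shared by AC010422.3, AC008440.2 (−2.41) and HIST1H2AC (CPM of 16.6, 8.83, 10.6 and 15.9 in nuclease-NT, nuclease-SMARCA4, YTHDF2-NT and YTHDF2-SMARCA4). Next were ZNF767P (1.23, adjusted p = 0.116), CPT1B (0.94), POMZP3 (1.28), MCOLN3 (0.90), PARP6 (0.76), PRKAB1 (0.57) and SMG1P3 (1.51). Without YTHDF2-NT 2 it called 1444 genes, 607 higher and 837 lower. Fold changes in that fit ranked with transcript length at a Spearman rho of 0.6 across 10486 genes. Across 10457 genes, which are not independent replicates, the guide effects of the nuclease and of YTHDF2 correlated at r = −0.166, and these comparisons share no library.

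YTHDF2 cells with the NT guide differed from nuclease cells with the same guide in the heat shock, unfolded protein and p53 lists. All 12 heat shock genes were higher (median 0.29, adjusted p = 2.51e-12, adjusted p = 0.024 with an estimated correlation). Over the list alone 9 passed, and over all genes 1, HSPA1B (0.72, SE 0.101, adjusted p = 0.0356), an inducible HSP70 whose counts can be shared with HSPA1A. HSP90AA1 was at 0.51, HSPB1 at 0.54 and DNAJB1 at 0.36. HSPA6, an inducible HSP70 outside the list, was called lower (−1.69). Unfolded protein response genes, chaperones of the endoplasmic reticulum, rose in 14 of 16 (median 0.21, adjusted p = 2.93e-08, adjusted p = 0.0291 with an estimated correlation), 7 over the list alone. HSPA5 was at 0.45 and HSP90B1 at 0.35. P53 targets were lower in 15 of 16 (median −0.29, adjusted p = 8.2e-10, adjusted p = 0.0411 with an estimated correlation), 10 over the list alone. PLK3 was at −0.93, FDXR at −0.46, SESN1 at −0.37 and CDKN1A, the cell cycle inhibitor p21, at −0.29. The nuclease-NT libraries, which had the highest p53 deviations, enter both this comparison and the nuclease guide comparison, so the p53 results are not independent.

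**Figure D4:**
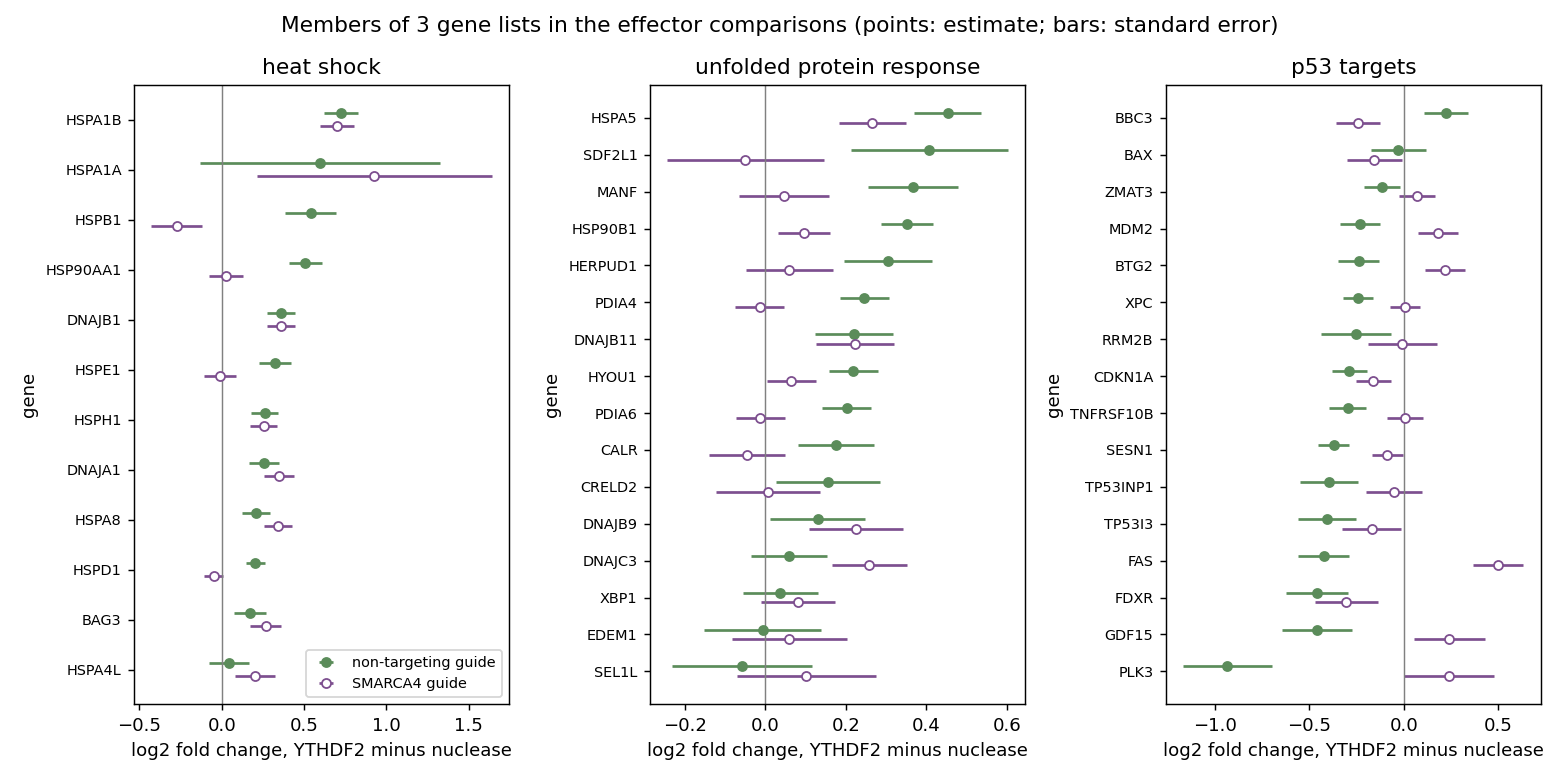
Log2 fold change of YTHDF2 over nuclease for the members of the heat shock, unfolded protein and p53 lists, with the NT guide (filled green) and the SMARCA4 guide (open purple), bars giving the standard error. All 12 heat shock genes are above 0 with the NT guide and 9 with the SMARCA4 guide, and 15 of 16 p53 targets are below 0 with the NT guide.

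G2/M genes were higher in 16 of 17 (median 0.17, adjusted p = 0.000456, adjusted p = 0.039 with an estimated correlation), with CENPE at 0.38 and TOP2A at 0.19. G1/S genes were lower in 14 of 17 (−0.10, adjusted p = 0.00616, adjusted p = 0.5 with an estimated correlation), with MCM5 at −0.36 and CDT1 at −0.26. Immediate early genes were higher in 13 of 16 (0.16, adjusted p = 0.0266, adjusted p = 0.614 with an estimated correlation). KLF6 was at 0.34 and EGR1 at 0.56. Ribosomal protein mRNAs were higher in 35 of 35 (0.29, adjusted p = 7.83e-13, adjusted p = 0.6 with an estimated correlation) and respiratory chain subunits in 21 of 22 (0.20, adjusted p = 0.000465, adjusted p = 0.771 with an estimated correlation). They were at 0.07 and −0.02 (adjusted p = 0.38) without YTHDF2-NT 1, and 0.12 and 0 (adjusted p = 0.942) with the length trend removed. Respiratory subunits were at 0.37 without YTHDF2-NT 2. With the preset correlation, heat shock, unfolded protein and p53 lists passed in each of 6 fits with 1 library left out. G2/M genes were at 0.10 without nuclease-NT 3 and lost the call without YTHDF2-NT 2 (0.06, adjusted p = 0.0565). G1/S genes lost it without YTHDF2-NT 2 (adjusted p = 0.192), and immediate early genes without YTHDF2-NT 2 (0.0626), YTHDF2-NT 3 (0.621) or nuclease-NT 1 (0.228).

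Across all comparisons, the calls that held with an estimated correlation were the heat shock, unfolded protein, p53 and G2/M lists with the NT guide and construct parts with both guides. Construct parts hold YTHDF2 itself, which the design sets apart between the effectors, so that call says nothing of the other members. With the length trend removed, histone genes also passed in the interaction and with the SMARCA4 guide. Calls of the first 4 lists at this threshold depended on single libraries, while with 1 library left out the medians ranged from 0.24 to 0.35 for heat shock, 0.18 to 0.27 for unfolded protein, −0.37 to −0.26 for p53 and 0.06 to 0.15 for G2/M genes. Heat shock genes lost that call without YTHDF2-NT 2 (adjusted p = 0.0608), YTHDF2-NT 3 (0.0874), nuclease-NT 1 (0.0543) or nuclease-NT 2 (0.0601). Unfolded protein genes lost it without YTHDF2-NT 1 (0.0514), YTHDF2-NT 2 (0.0608), YTHDF2-NT 3 (0.0911), nuclease-NT 1 (0.0543) or nuclease-NT 2 (0.0797). P53 targets lost it without YTHDF2-NT 1 (0.0798), YTHDF2-NT 2 (0.228), YTHDF2-NT 3 (0.0916), nuclease-NT 2 (0.0797) or nuclease-NT 3 (0.0833). For G2/M genes it was lost without YTHDF2-NT 2 (0.427), YTHDF2-NT 3 (0.0916), nuclease-NT 1 (0.0543), nuclease-NT 2 (0.0921) or nuclease-NT 3 (0.0991). With the length trend removed the p53 (−0.27) and unfolded protein (0.21) lists were at an adjusted p of 0.0512 and the G2/M list (0.13) at 0.0514. Construct parts (median 0.08, mean 0.975, adjusted p = 2.57e-18, adjusted p = 0.0178 with an estimated correlation) lost it without YTHDF2-NT 2 (0.0608), and their median was 0.16 without YTHDF2-NT 1 and 0.04 without nuclease-NT 1.

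Lists not called with the NT guide were mitochondrially encoded mRNAs (−0.18, adjusted p = 0.0773), integrated stress (0.07, adjusted p = 0.131), interferon response (0.11, adjusted p = 0.295) and NMD targets (0.06, adjusted p = 0.295). Histone genes (−0.18, adjusted p = 0.295, HIST1H2AC −0.65), the m6A machinery (0.01, adjusted p = 0.699) and decay factors (−0.05, adjusted p = 0.612) did not pass either. Median and mean differed in sign for BAF subunits (0.03 and −0.05, adjusted p = 0.917), hypoxia genes (−0.001 and 0.02, adjusted p = 0.917), NMD factors (−0.05 and 0.03, adjusted p = 0.921). They also did for the neighbours (−0.02 and 0.01, adjusted p = 0.838), cholesterol synthesis (0.004 and −0.02, adjusted p = 0.612), fibroblast markers (0.02 and −0.06, adjusted p = 0.917) and epithelial markers (0.45 and −0.23, adjusted p = 0.811, KRT17 −1.75). Blood markers had a median of 0.03 with a test toward lower values (adjusted p = 0.917). Mitochondrially encoded mRNAs passed without YTHDF2-NT 2 (−0.34, adjusted p = 0.0015) or nuclease-NT 3 (−0.33, adjusted p = 0.00016). NMD targets passed without YTHDF2-NT 2 (0.12, adjusted p = 0.00102), and interferon genes (0.205) and the m6A machinery (0.09) without YTHDF2-NT 1 (both at an adjusted p of 0.035). With the length trend removed mitochondrially encoded mRNAs (−0.25, adjusted p = 0.00387), histone genes (−0.275) and integrated stress genes (0.10) passed, the last 2 at an adjusted p of 0.0349.

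Apart from YTHDF2, 7 genes were called with the NT guide. NGFR, a neurotrophin receptor, rose from 2.44 ± 0.78 to 7.68 ± 0.939 CPM (SD, n = 3) and HSPA1B from 792 ± 35.3 to 1310 ± 175 CPM. HSPA6, a strictly inducible HSP70, was lower, at 20 ± 4.31 against 6.16 ± 1.84 CPM. Also lower were INPP5D, a phosphoinositide phosphatase (9.24 ± 0.573 against 3.85 ± 0.688), CPT1B (12.4 ± 1.07 against 7.37 ± 0.407), UAP1L1 (37.7 ± 4.85 against 22.8 ± 0.784) and SLC12A4, a potassium chloride cotransporter (27.6 ± 0.599 against 17.6 ± 1.75). Their log2 fold changes were 1.68 for NGFR, −1.69 for HSPA6, −1.26 for INPP5D, −0.75 for CPT1B, −0.72 for UAP1L1 and −0.65 for SLC12A4, at edgeR adjusted p-values of 0.0356 to 0.0459. Over 18 alternatives SLC12A4 ranged from −1.28 to −0.60 and INPP5D from −1.39 to −0.80. Each of the 7 genes lost its call in 7 or 8 of these alternatives. TP53INP2 (−0.64) and AEN, a p53-induced nuclease (−0.64, 218 against 140 CPM), came next at an adjusted p of 0.0756. At an unadjusted p under 0.05 there were 1775 genes, and groups did not overlap for 12.8% where chance gives 10%. The count was 1610 (937 higher, 673 lower) without YTHDF2-NT 2, 16 without YTHDF2-NT 1, 1 without YTHDF2-NT 3, nuclease-NT 2 or nuclease-NT 3, and 2 without nuclease-NT 1. In the fit without YTHDF2-NT 2 the fold changes ranked with transcript length at a Spearman rho of −0.62 across 10486 genes.

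With the SMARCA4 guide, YTHDF2 cells again had higher heat shock mRNAs than nuclease cells, in libraries that the comparison with the NT guide does not use. They were higher in 9 of 12 (median 0.26, adjusted p = 3.72e-06, adjusted p = 0.115 with an estimated correlation), 6 over the list alone. HSPA1B was at 0.70, DNAJB1 at 0.36 and HSPA8 at 0.34. Not all members repeated: the effector difference with this guide minus that with the NT guide was −0.81 for HSPB1 and −0.48 for HSP90AA1. Histone genes were higher in 11 of 11 (0.48, adjusted p = 6.64e-05, adjusted p = 0.115 with an estimated correlation, and 0.0357 with the length trend also removed), with HIST1H2AC at 0.86 and HIST1H1C at 0.48. NMD targets were higher in 14 of 20 (0.18, adjusted p = 0.000109, adjusted p = 0.518 with an estimated correlation). SNHG1 was at 0.40 and SRSF6 at 0.46. The nuclease-SMARCA4 libraries also enter the nuclease guide comparison, where histone genes and NMD targets were lower. Results of these comparisons are thus not independent. With the NT guide the effector medians were −0.18 for histone genes and 0.06 for NMD targets, and neither list was called. Immediate early genes were higher in 14 of 16 (0.22, adjusted p = 0.00413), with FOS at 0.96. The m6A machinery was higher in 15 of 18 (0.08, adjusted p = 0.0352), with WTAP at 0.21, and unfolded protein genes in 12 of 16 (0.06, adjusted p = 0.0431), with HSPA5 at 0.27, each of these 3 lists at adjusted p = 0.422 with an estimated correlation. Fibroblast markers were lower in 5 of 5 (−0.38, adjusted p = 0.0183, adjusted p = 0.263 with an estimated correlation). FBLN1 was at −0.34 and COL1A1 at −0.24. Construct parts, among them YTHDF2 itself, were higher in 5 of 5 (0.52, adjusted p = 8.12e-32, adjusted p = 0.00279 with an estimated correlation). Over the list alone 4 passed, YTHDF2, SNRPA (0.67, adjusted p = 0.00417), HBEGF (0.52, adjusted p = 0.0061) and YTHDF1 (0.23, adjusted p = 0.0123).

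Ribosomal protein mRNAs were lower in 35 of 35 (−0.20, adjusted p = 5.17e-09, adjusted p = 0.546 with an estimated correlation), respiratory chain subunits in 22 of 22 (−0.17, adjusted p = 0.000109, adjusted p = 0.678 with an estimated correlation) and mitochondrially encoded mRNAs in 13 of 13 (−0.34, adjusted p = 0.000109, adjusted p = 0.517 with an estimated correlation). MT-CO3 was at −0.42 and MT-CO1 at −0.41. The direction of the ribosomal and respiratory lists was opposite to that with the NT guide, and with the length trend removed their medians were −0.12 and −0.08. Calls were lost without YTHDF2-SMARCA4 1 for mitochondrially encoded mRNAs (−0.21, adjusted p = 0.055), immediate early genes (0.103), the m6A machinery (0.0983) and unfolded protein genes (0.195). They were lost without nuclease-SMARCA4 1 for NMD targets (0.124), unfolded protein genes (0.124) and the m6A machinery (0.0678), and without nuclease-SMARCA4 2, or with the length trend removed, for the m6A machinery (0.0651 and 0.123). Mitochondrially encoded mRNAs were at −0.19 without nuclease-SMARCA4 2, and unfolded protein genes at 0.10 without YTHDF2-SMARCA4 3.

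Lists not called with this guide were NMD factors (0.10, adjusted p = 0.0562), BAF subunits (0.06, adjusted p = 0.592), the neighbours (−0.04, adjusted p = 0.539), and decay factors (0.03, adjusted p = 0.287). The same held for interferon response (0.10, adjusted p = 0.851), integrated stress (−0.10, adjusted p = 0.256), G1/S genes (−0.04, adjusted p = 0.533) and epithelial markers (−0.01, adjusted p = 0.971). Median and mean differed in sign for p53 targets (−0.001 and 0.02, adjusted p = 0.934, FAS 0.50), hypoxia genes (−0.02 and 0.01, adjusted p = 0.934, ADM 0.63) and cholesterol synthesis (−0.03 and 0.01, adjusted p = 0.851). They also did for G2/M genes (−0.03 and 0.03, adjusted p = 0.992) and blood markers (−0.01 and 0.17, adjusted p = 0.934). Hypoxia genes passed without YTHDF2-SMARCA4 1 (−0.24), nuclease-SMARCA4 1 (0.19) or nuclease-SMARCA4 3 (−0.17), with opposite signs. NMD factors passed without nuclease-SMARCA4 2 (adjusted p = 0.0269) or with the length trend removed (0.0373), and integrated stress without nuclease-SMARCA4 1 (−0.17, adjusted p = 0.00146).

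YTHDF2 was the only gene called by edgeR with the SMARCA4 guide. HSPA1B (0.70, 713 against 1160 CPM), PNN (0.51) and CLK1, a kinase of splicing factors (0.62), followed at an adjusted p of 0.0663. Then came MAT2A, which makes S-adenosylmethionine (0.76, 99.4 against 169 CPM), PCK2, a mitochondrial enzyme of gluconeogenesis (−0.57, 69.9 against 47.2 CPM), THAP9-AS1 (0.64), PALD1 (−0.48), AHI1 (0.48) and ARRDC3 (1.004, 29.4 against 58.9 CPM). At an unadjusted p under 0.05 there were 1867 genes, and 26.7% of all genes had no overlap between the groups, where chance gives 10%. A fit of the 6 libraries compared called 660 genes (346 higher, 314 lower) and DESeq2 91. Without YTHDF2-NT 1, 2 and 3, which are not in this comparison either, 70, 21 and 2 genes were called. Across 10457 genes the effector differences with the NT guide and with the SMARCA4 guide correlated at r = −0.009, and they share no library. YTHDF2 is among these genes, and its large rise with both guides pulls r upward. The Spearman rho, which depends less on a single gene, was −0.087, and 46.7% of genes had the same sign. The labels do not say whether the effectors were grown in the same batch, so effector and batch cannot be told apart.

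Per transcript, edgeR called 1 of 49518 in the nuclease guide comparison, TMEM185A-208 (adjusted p = 0.0428, 7.38 to 0 CPM). In the YTHDF2 guide comparison it called 3, 1 of CACNA2D2 (ENST00000360963.7, 5.18 to 0 CPM, adjusted p = 0.0109), 1 of LRRC4B (ENST00000599957.5, 0 to 6.11 CPM, adjusted p = 0.0308) and 1 of FHL2 (ENST00000322142.12, 4.24 to 0 CPM, adjusted p = 0.0455). Each stands against a group at 0, where kallisto can move a gene's counts between its transcripts, so no fold is given. The nuclease count was 0 in each fit that left out 1 compared library, and the YTHDF2 count was 67 without YTHDF2-NT 2 and 1 without YTHDF2-SMARCA4 1.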

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

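The tests of construct RNA, of less construct delivered and of decay of 1 reporter were chosen after the results were seen, as were removal of the length trend, the spread between libraries set beside matched lists, the separate tests of the ribosomal and respiratory lists and the standard error set beside the value without YTHDF2-NT 1.

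Guide effects differed between the effectors, by the interaction test with a preset correlation, for 5 gene lists: ribosomal proteins (−0.49), respiratory chain subunits (−0.40), p53 targets (0.27), G2/M genes (−0.14) and histone genes (0.79), each as the median of the YTHDF2 effect minus the nuclease effect. With an estimated correlation none passed (adjusted p from 0.278 to 0.662), but with the length trend removed as well histone genes did (median 0.896, adjusted p = 0.04).

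The ribosomal and respiratory lists hold short mRNAs, and the libraries differ in a trend on transcript length. Random lists matched on length had a median of −0.31 for the ribosomal list (95% range −0.38 to −0.22), a range too narrow for genes that vary together. Set against the spread between libraries, the list lay at −0.22 (SE 0.053) relative to its matched genes, and from −0.255 to −0.184 with 1 library left out. The length trend could thus account for much of the −0.49 but not for all of it. Genes were not matched on GC content, on which the libraries also differ, so a part of GC in the remainder was not tested. For the respiratory list the matched median was −0.34 (range −0.42 to −0.23), which holds the observed −0.40, so this difference may be a length trend of the libraries, while an effect of the effectors stays open and untested. Without YTHDF2-NT 1 the ribosomal median was −0.28 (SE 0.126), too close to the bound of −0.2 set in advance to say whether that library alone is the source.

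P53 targets were lower in nuclease-SMARCA4 (−0.28) and in YTHDF2-NT (−0.29) than in nuclease-NT, the group that both comparisons share. With an estimated correlation the camera adjusted p was 0.143 for the first and 0.0411 for the second. That second call was kept in 1 of 6 fits with 1 library left out. The activity of p53 itself was not measured. Lists matched on length gave medians of 0.01 (0.009, range −0.09 to 0.09) and 0.004 (range −0.08 to 0.10), and relative to matched genes p53 targets lay at −0.30 and −0.31 (SE 0.067 between libraries for each), which argues against the length trend. Less construct RNA is one candidate explanation for the first, where firefly was at −0.71 (95% interval −1.12 to −0.31), but it cannot be told apart from the guide. For the second, firefly at 0.09 (0.087, interval −0.32 to 0.49) and SNRPA at 0.05 (interval −0.32 to 0.41) argue against a loss of that size in these RNAs. Renilla at −0.37 (interval −0.75 to 0.01) leaves a smaller loss, or a loss of renilla alone, open. The labels do not say how these RNAs relate to the effectors, so they cannot decide whether there was less effector RNA. A state particular to the nuclease-NT cultures, or an effect of the nuclease with this guide, stays open, since the labels give no culture batch.

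Firefly, renilla and SNRPA counts were all lower in nuclease-SMARCA4 than in nuclease-NT. SNRPA-206 was lower relative to SNRPA-201 by −0.72 (SE 0.29), but that model holds most SNRPA counts, so its fall was known beforehand, and the labels do not give the construct parts, so less construct delivered or expressed in these 3 cultures stays open. The ratio of firefly to renilla moved 1.12-fold (SE 0.094), against decay of 1 reporter directed by the guide. Among 277 genes of like length the median was 0.01 (0.013, 95% range −0.38 to 0.35), so a length trend of that size is not seen. Guide and culture cannot be told apart here, since the labels give no culture batch.

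The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For the nuclease guide comparison 1 of 10 splits, the real one, called as many genes (real 1, highest other 0). The same held for the effectors with the NT guide, 1 of 10 (real 8, highest other 1), and with the SMARCA4 guide, 1 of 10 (real 1, highest other 0). For transcripts, 4 of 10 splits called as many in the nuclease comparison (real 1, highest other 4) and 3 of 10 in the YTHDF2 comparison (real 3, highest other 6). A real count of 0 is met by any split, so for genes in the YTHDF2 guide comparison (10 of 10, highest other 0) and in the interaction (100 of 100 splits drawn from 200, highest other 2) the splits say nothing about chance.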

How the results depend on the processing

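Removal of length or GC trends, and leaving out libraries outside a comparison, were chosen after the results were seen. The counts of genes called depended on the setting, and except where stated the cause was not tested. In the order nuclease guide, YTHDF2 guide, interaction, effector with the NT guide and effector with the SMARCA4 guide, edgeR called 1, 0, 0, 8 and 1 genes. Without a filter on low counts it called 333, 214, 493, 360 and 296, and DESeq2 called 129, 1, 53, 103 and 91. With only the 6 libraries compared, the nuclease guide count was 550 and that of the effector with the SMARCA4 guide 660, fits without the more variable YTHDF2-NT libraries. Length-scaled TPM counts gave 0 for the nuclease guide and 1 for the effector with the NT guide, limma-trend 0 for the nuclease guide and 2 for the interaction, and protein-coding genes alone 0 for the nuclease guide and 5 for the effector with the SMARCA4 guide. With the length trend removed the counts were 23 (nuclease guide), 3 (interaction), 14 and 13 (effector with the NT and SMARCA4 guides), with GC and length trends removed 100, 4, 23 and 10, and with the length trend removed and YTHDF2-NT 2 left out 210, 721, 539, 690 and 139 over all 5. With 1 library left out the counts ranged from 0 to 44, 0 to 1585, 0 to 1444, 1 to 1610 and 1 to 70. The counts of 1585, 1444 and 1610 came from the fit without YTHDF2-NT 2. In it fold changes ranked with transcript length at a Spearman rho of 0.6, 0.6 and −0.62.

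The SMARCA4 log2 fold change with the nuclease turned to 0.003 without a filter and ranged from −0.051 to 0.042 with 1 library left out (0.013 without nuclease-NT 2, 0.003 without nuclease-NT 3 and 0.042 without nuclease-SMARCA4 3). Over all 21 alternatives it ranged from −0.157 (limma-trend on TPM) to 0.042. With YTHDF2 it ranged from −0.29 to −0.11, or to −0.31 (length-scaled TPM counts) over all 18, and adjusted p over all alternatives from 0.0485 to 1. Lists called were 11, 7, 5, 9 and 11, falling to 0, 0, 0, 5 and 1 with an estimated correlation and 3, 0, 0, 5 and 3 with fry, and the interaction gave 8 with the length trend removed. With 1 library left out they were 10 to 13, 6 to 8, 5 to 9, 8 to 10 and 8 to 12. Transcripts called were 469 (nuclease guide) and 308 (YTHDF2 guide) with DESeq2 and 0 and 0 with the 6 libraries, and ranged from 0 to 0 and from 1 to 67 with 1 library left out. YTHDF2 kept its call in all 18 and 21 alternatives, and ZNF767P in 12 of 20. The YTHDF2 log2 fold change ranged from 4.49 to 6.995 with the NT guide and from 4.48 to 6.95 with the SMARCA4 guide. Totals from 9207196 counts and 3 libraries a group limit what is seen. The simulated data had 1 spread per gene for all groups. In them 18% of the genes with the smallest simulated fold were recovered in the nuclease comparison and 14% in the YTHDF2 comparison.

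Replicate numbers did not pair the samples: correlations of the deviations of same-numbered libraries were 0.072, −0.108 and 0.126 in the nuclease comparison and −0.231, 0.084 and 0.006 in the YTHDF2 comparison. With the replicate number as a block the gene counts were 1, 0, 0, 1 and 1, the transcript counts 0 and 0, and the lists called 10, 6, 5, 10 and 10. List tests with the block were chosen after the results were seen. With the preset correlation the block ended the calls of unfolded protein genes (nuclease guide, adjusted p = 0.0655, effector with the SMARCA4 guide, 0.0514), immediate early genes (YTHDF2 guide, 0.0541) and G2/M genes (interaction, 0.064), and added construct parts (interaction, 0.0434) and mitochondrially encoded mRNAs (effector with the NT guide, 0.0137). With the block and an estimated correlation, heat shock (adjusted p = 0.0982), unfolded protein (0.133) and G2/M genes (0.276) did not pass for the effector with the NT guide, and p53 targets did (0.0368).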

Other observations

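The fits of 6 libraries were planned, while the genes named from them were chosen after their values were seen. In the fit of the nuclease libraries alone, which called 550 genes between the guides, the raised genes included NDRG1 (0.79, adjusted p = 0.000639), RHOB, a small GTPase (0.64, adjusted p = 0.00434), and the annexin pair S100A10 (0.41) and ANXA2 (0.34). PPM1D, a p53-induced phosphatase (−0.57), DDB2 (−0.77), the long noncoding RNA PVT1 (−0.79) and HSPA6 (−1.23) were lower, at adjusted p-values of 0.0117 to 0.019. By list, 31 of 35 ribosomal protein mRNAs, 6 of 19 hypoxia and glycolysis genes and 3 of 22 respiratory subunits rose, and 5 of 16 p53 targets, 3 of 10 histone genes, 3 of 20 NMD targets and 2 of 17 G1/S genes fell. In each other list at most 2 members passed. Renilla (−0.89, adjusted p = 0.0117), firefly (−0.72, adjusted p = 0.0244), SNRPA (−0.695, adjusted p = 0.0244) and SMG6 (−0.335, adjusted p = 0.0455) passed in this fit. Fold changes ranked with transcript length at a Spearman rho of −0.3 across 10487 genes.

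Between the effectors with the SMARCA4 guide, the fit of 6 libraries called 660 genes. It shares the nuclease-SMARCA4 libraries with the fit of the nuclease libraries alone, so the results of these fits are not independent. Higher in the YTHDF2 cells were ARRDC3, an arrestin family gene (1.01, adjusted p = 0.00048), MAT2A (0.76, adjusted p = 0.00048), SNRPA (0.67, adjusted p = 0.0177), PNN (0.51), CLK1, a kinase of splicing factors (0.63), LUC7L3 (0.51), NKTR (0.58), PRPF4B (0.44) and SRRM2 (0.40). PCK2 (−0.57) and IDH2 (−0.40), enzymes of mitochondria, were lower. By list, 5 of 12 heat shock genes, 6 of 20 NMD targets and 4 of 10 histone genes rose, and 17 of 35 ribosomal protein mRNAs fell, with at most 2 members past the test in each other list. Fold changes ranked with transcript length at a rho of 0.29 across 10486 genes. The GC trend of the libraries also parted these groups, at −0.37, −0.47 and −0.33 in YTHDF2-SMARCA4 against 0.03, 0.53 and 0.13 in nuclease-SMARCA4. Its share in this fit was not tested.

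A ZPR1 transcript model of 598 bases, which holds a run of 35 T, had the highest mean TPM of all targets (20378.2), from 14900 to 28313 in the libraries, while the other transcripts of ZPR1 together had 59.0 to 92.4. The next highest were SNRPA-206 (10132.9) and the BCYRN1 transcript (9671.9), and 193 transcripts hold a run of A or T of at least 31 bases.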
